A study of Rhodotorula toruloides with 2 samples.

How the data were processed

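RNA sequencing of wild-type Rhodotorula toruloides from chemostat culture was compared between 2 libraries, 1 labelled Pi-limited and 1 labelled Pi-replete. Per the labels' protocols, the working volume was 2.0 litre, 40 ml of culture was sampled onto ice for each RNA preparation, total RNA was extracted with RNAiso Plus, and libraries were made with standard Illumina protocols. The labels mention no replicate cultures. Cufflinks and DESeq are named in the submitters' processing notes without a role or version. The aligner, the genome build and whether strand was used in counting are not given in the sources used here.

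The data were 1 table that the authors deposited, with a line per listed gene. Per the file headers it holds the raw count per gene in each library, the RPKM (reads scaled by gene length and library total) in each library, the log2 ratio of the RPKM values, a p-value and a false discovery rate (FDR), the gene length, and best BLAST and KEGG descriptions. The deposited count columns were whole numbers. Dividing each deposited count by its length and RPKM gave the same total for every gene of a library, 5892590 counts for the library labelled Pi-limited and 5641377 for the library labelled Pi-replete, and these served as library totals. The deposited RPKM of a gene with 0 counts was 0.01, which held for 11 listed genes in the library labelled Pi-limited and 4 in the library labelled Pi-replete. The deposited log2 ratio was that of the library labelled Pi-replete over the library labelled Pi-limited and equalled the ratio of the RPKM columns. Here it was recomputed from the RPKM values as the library labelled Pi-limited over the library labelled Pi-replete. Listed genes took 13.28% of the total in the library labelled Pi-limited (exact 95% interval 13.25 to 13.31) and 16.46% in the library labelled Pi-replete (16.43 to 16.50).

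The values show a filter at an absolute log2 ratio of at least 1 and an FDR of at most 0.001. For the 1269 genes with a p above 1e-200, the authors' deposited p-value lay within 1% of 2 times the smaller tail of the Audic-Claverie distribution for the recovered totals, a test of counting error that allows for no spread between cultures. Multiplying out FDR and p gave whole ranks for 7970 tested genes, so 17.6% of the genes tested were listed. By that number, 2146 genes at or under the largest listed FDR were not listed, which leaves a ratio under 2-fold. No p-value was added here, since 1 library per condition gives no spread to test against, and genes are not replicates.

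For each gene the fold of counts, each divided by its library total, was given with an exact 95% interval (Clopper-Pearson, from the conditional binomial of the 2 counts). For a gene at 0 the bound was set against a floor of 3 counts per library, which corresponds to 0.509 CPM (counts scaled to the library total) in the library labelled Pi-limited and 0.532 in the library labelled Pi-replete. Intervals of folds, and floors, cover counting error only, as no molecular identifiers are mentioned. Intervals of a share of genes or pairs, or of a gap between shares, take genes or pairs as independent draws. They cover neither counting error nor spread between cultures. The deposited length was a multiple of 3 for 99.4% of genes, so it is a coding length without untranslated regions. Without strand information, reads of overlapping or antisense genes cannot be told apart, and near-identical copies may share reads. For 111 listed genes the best hit is a proteophosphoglycan, and some of these carry unrelated KEGG descriptions. Sequences were not compared, so whether any of them are copies that share reads is not known. All 1402 identifiers matched the RHOziaDV1.0 gene table of strain NP11, which gave no gene names beyond the identifiers. It was used only for which genes neighbour each other, and no coordinates are given because the authors' build is not given in the sources used here. Gene names are therefore the deposited best-hit descriptions.

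Before the data were examined, the groups, the comparison, 23 gene lists with their search patterns, the rule for named genes and most of the other settings tried were fixed. Lists were matched to the BLAST and KEGG descriptions. Of the 23 lists, 2 had no listed member, and 1 had fewer than 5 and is given as counts only. For the rest, the median log2 ratio was placed among 10000 random lists of the same size drawn from the listed genes and matched on mean expression in 10 strata. This percentile describes these libraries. No enrichment against the genome was made. The named genes were the 8 genes per direction with the largest absolute log2 ratio among those with an informative description and at least 100 counts in the library with more, the 3 members of each list with the largest absolute log2 ratio and at least 50 counts, every phosphate acquisition member, and the key lipid genes (fatty acid synthase, acetyl-CoA carboxylase, ATP-citrate lyase, malic enzyme, diacylglycerol acyltransferase, perilipin, delta-9 and delta-12 desaturases). A gene that several parts of the rule name counts under each, and the text does not print every gene of the first and second parts. The rule gave 82 genes, and other named genes were chosen after their values were seen. The fixed check of the labels was the direction of the phosphate acquisition list, and it went against them, so libraries are called by their labels throughout.

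The other settings fixed in this way were an absolute log2 ratio of at least 2, an FDR of at most 1e-10, at least 100 counts in the library with more, equal totals over the listed genes, centring on the median ratio of the listed genes, a pseudocount of 1 or 0.1 on RPKM, leaving out genes in more than 1 list, and random lists not matched on expression. In the rescaled ratios a count of 0 was replaced by 0.5. Leaving out list members described with another function (80 memberships) and the percentile of the number of members higher were added after the data were seen. The members left out were picked by hand from their descriptions. Some with more than 1 description, such as RHTO_05069, RHTO_01519 and RHTO_04785, were kept.

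The calculations were tested on simulated Poisson counts for the 1402 genes, with 200 changed and no spread between cultures. The FDR was taken over these 1402 genes and not over the 7970 tested. The results therefore check the calculations under counting error alone and give no error rates for 1 library per condition. At an FDR of 0.001 the counting test called 76.1% of genes changed 2-fold, 97.3% of those changed 4-fold, 100% of those changed 8-fold and 0% of unchanged genes, and the intervals held the true fold for 95.8%, 98.6%, 98.2% and 96.1% of these. Of simulated lists with 13 higher and 2 lower genes, the median's percentile fell outside 2.5 to 97.5 for 24% and that of the number higher for 86%. For lists with 2 higher and 13 lower genes these were 68% and 100%, and for random lists 5% with either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.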

Results

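The oleaginous red yeast Rhodotorula toruloides (also named Rhodosporidium toruloides), a basidiomycete that can store much of its biomass as triacylglycerol, was grown in chemostats, continuous cultures held at a constant volume, with inorganic phosphate (Pi) either limiting or replete. Total RNA from 1 culture sample per condition was sequenced, giving 1 library labelled Pi-limited and 1 library labelled Pi-replete. With no replicates, the spread between cultures was not measured, and no difference has a replicate check. The library totals recovered from the deposited values were 5892590 counts for the library labelled Pi-limited and 5641377 for the library labelled Pi-replete. The comparison of the 2 libraries asks which transcripts differ with Pi supply in a yeast studied for its lipid accumulation, and the authors' deposited table lists 1402 genes that passed their thresholds.

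Most listed genes that take up phosphate or release it from organic compounds were lower in the library labelled Pi-limited than in the library labelled Pi-replete. A sodium:Pi symporter (RHTO_01284) had 22 counts in the library labelled Pi-limited and 5797 counts in the library labelled Pi-replete, a 275-fold difference (95% interval 182 to 440). Listed members of the amino acid biosynthesis list and of the beta-oxidation, lipase and peroxisome list were also mostly higher in the library labelled Pi-replete, whereas those of the DNA replication, chromatin and cell cycle list were mostly higher in the library labelled Pi-limited. In fungi the phosphate acquisition genes are known to be induced by Pi shortage, so their direction here ran against the labels. No library was moved to another group for this reason, and every direction is given by the label that a library carries. Folds compare counts divided by each library's total, and their 95% intervals cover counting error only.

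Of the 16 listed members of the phosphate acquisition and storage list, 14 were lower and 2 were higher in the library labelled Pi-limited. Their median log2 ratio was -2.35 (labelled Pi-limited over labelled Pi-replete), at percentile 0.02 among 10000 random lists of the same size matched on mean expression. Both transporters of the fungal Pi:proton symporter (PHS) family followed the sodium:Pi symporter: RHTO_06822 was 54.6-fold (38.3 to 80.6) and RHTO_01549 was 34.1-fold (22.5 to 54.1) higher in the library labelled Pi-replete. An alkaline phosphatase (RHTO_03053) had 9 and 692 counts, 80.3-fold (42.1 to 176) higher in the library labelled Pi-replete, and a gene described both as a phosphate transporter and as a T2 ribonuclease (RHTO_05069) had 4 and 251 counts, 65.5-fold (25.3 to 242) higher there. The 4 members described as acid phosphatases alone (RHTO_07386, RHTO_01362, RHTO_07160 and RHTO_04431) were 9.01-, 4.98-, 4.55- and 2.30-fold higher in the library labelled Pi-replete. A glycerophosphodiester phosphodiesterase (RHTO_01245), which degrades deacylated phospholipids, was 5.22-fold (4.28 to 6.43) higher there. The betaine lipid synthase (RHTO_03325), which makes a membrane lipid without phosphorus, was 4.70-fold (3.45 to 6.52) higher in the library labelled Pi-replete, and PHO81 (RHTO_02991), an inhibitor of the cyclin-dependent kinase of the phosphate response, was 2.65-fold (2.36 to 2.97) higher. An ADP-ribose pyrophosphatase (RHTO_05022) and an inosine triphosphate pyrophosphatase (RHTO_07202), which hydrolyse nucleotides, were 5.74- and 2.56-fold higher in the same library. The 2 members with the other direction were a phytase that is also described as an acid phosphatase (RHTO_00655), with 15 counts in the library labelled Pi-limited and 1 in the library labelled Pi-replete (14.4-fold, 2.21 to 605), and a second ADP-ribose pyrophosphatase (RHTO_05023, 5.63-fold, 3.70 to 8.90).

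**Figure D1:**
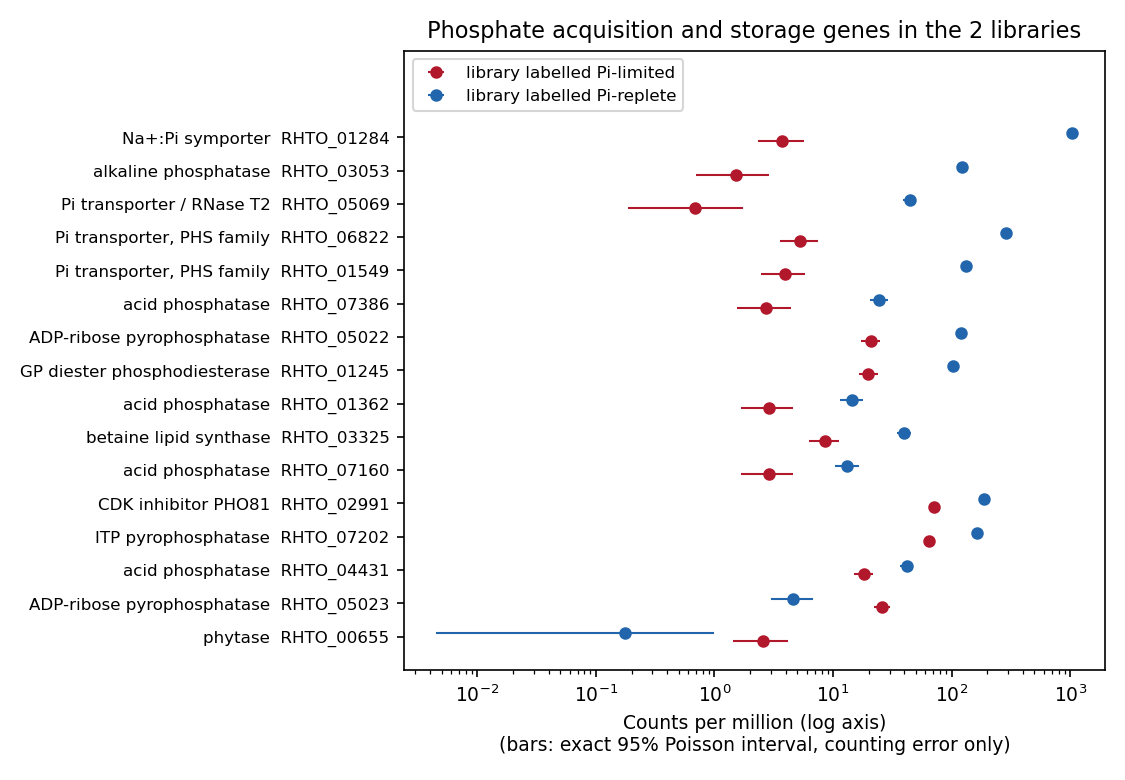
Counts divided by the library total (CPM), on a log axis, of the 16 listed members of the phosphate acquisition and storage list in the library labelled Pi-limited (red) and the library labelled Pi-replete (blue), 1 library each, with exact 95% Poisson intervals that cover counting error only. For 14 genes the blue point lies to the right of the red one, and for the phytase and 1 ADP-ribose pyrophosphatase it lies to the left.

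Of the 1402 listed genes, 817 were higher and 585 lower in the library labelled Pi-limited (58.3% higher, exact 95% interval 55.6 to 60.9). That interval takes genes as independent draws. The largest differences had the other balance. Among 474 genes that differed at least 4-fold, 197 were higher and 277 lower in the library labelled Pi-limited, and among 105 genes that differed at least 16-fold, 29 were higher and 76 lower. Centring the ratios on the median of the listed genes shifted every gene by -1.10 on the log2 scale and left 181 genes at least 2-fold higher against 585 lower (23.6% higher), while equal totals over the listed genes shifted every gene by 0.31 and gave 817 against 436 (65.2% higher). Genes under a 2-fold difference are not in the table, so a shift of all genes can only remove members of 1 direction, and these splits, like those given below as set by construction, do not show how an unfiltered table would divide. In the authors' deposited table the smallest absolute log2 ratio was 1.0003 and the largest FDR was 9.75e-04, and that test compares these 2 libraries, not the conditions.

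The glyoxylate cycle, by which yeasts build sugars from acetyl units, was represented by isocitrate lyases and malate synthase. One isocitrate lyase (RHTO_05768) had 47 counts in the library labelled Pi-limited and 6064 in the library labelled Pi-replete, 135-fold higher in the latter (101 to 184). A second isocitrate lyase (RHTO_03507) was 4.66-fold (4.20 to 5.17) and malate synthase (RHTO_01459) 7.87-fold (6.88 to 9.02) higher in the library labelled Pi-replete. Phosphoenolpyruvate carboxykinase (RHTO_07480), the committed enzyme of gluconeogenesis, was 4.21-fold (3.89 to 4.55) higher there. A shorter gene beside RHTO_05768 that is also described as isocitrate lyase (RHTO_05767), chosen after its values were seen, had the other direction, with 102 and 32 counts. In all, 4 of the 10 members of the tricarboxylic acid and glyoxylate cycles were higher in the library labelled Pi-limited and 6 were lower (median percentile 13.4), or 4 and 4 without genes in more than 1 list. The 8 members of glycolysis and gluconeogenesis divided into 5 higher and 3 lower (median percentile 97.2), and the 5 higher ones were all described as alcohol dehydrogenases or their relatives, such as RHTO_01725 (5.09-fold, 3.90 to 6.73). This list turned to 2 higher and 3 lower with members of at least 100 counts, at an FDR of at most 1e-10 and without members described with another function. No listed gene matched the pentose phosphate pathway list. Of the 5 oxidative phosphorylation members, 4 were higher in the library labelled Pi-limited (1 higher and 1 lower at 2-fold or more after median centring), among them the cytochrome oxidase assembly factors COX11 (RHTO_02091, 2.54-fold, 2.18 to 2.98) and COX15 (RHTO_06903, 2.39-fold, 2.26 to 2.53), and an NADH dehydrogenase (RHTO_03998) was 10.7-fold (8.74 to 13.3) higher in the library labelled Pi-replete.

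Lipid genes went both ways. ATP-citrate synthase (RHTO_03915), which supplies cytosolic acetyl-CoA for fatty acid synthesis, had 13087 counts in the library labelled Pi-limited and 3342 in the library labelled Pi-replete, 3.75-fold higher in the former (3.61 to 3.90). Malic enzyme (RHTO_03795), a source of NADPH, had the other direction and was 3.62-fold (3.30 to 3.99) higher in the library labelled Pi-replete. The fatty acid synthesis and precursor list had 10 members higher and 6 lower in the library labelled Pi-limited (median percentile 95.9), or 1 and 6 after median centring, by construction. Among members that differed at least 4-fold, 1 was higher and 4 were lower. Of these 16 members, 10 were dehydrogenases or reductases described with another function as well. Fatty acid synthase, acetyl-CoA carboxylase, diacylglycerol acyltransferase, perilipin and the delta-9 and delta-12 desaturases matched 0 listed descriptions and are not analysed here. Of 3 triacylglycerol members, 1 was higher and 2 were lower in the library labelled Pi-limited. By construction, this became 1 and 0 with equal totals and 0 and 2 after median centring. A glycerol-3-phosphate dehydrogenase (RHTO_07665, 2.38-fold, 2.22 to 2.55) was higher in the library labelled Pi-replete. It is described as EC:1.1.5.3 and matched the list by wording, and a role in triacylglycerol assembly was not tested. A lipin-type phosphatidate phosphatase (RHTO_04894, 2.11-fold, 1.86 to 2.39) was also higher there. A gene described as a lysophospholipid acyltransferase and as the RNA polymerase-associated protein CTR9 was higher in the library labelled Pi-limited (RHTO_01519, 3.21-fold, 2.54 to 4.09). The beta-oxidation, lipase and peroxisome list had 10 members higher and 27 lower in the library labelled Pi-limited, or 10 and 16 with equal totals. Without the 12 members described with another function, 6 were higher and 19 were lower. The number higher of the full list lay at percentile 0.01 of random lists, a measure added after the data were seen. The median of the full list lay at percentile 5.84. An esterase of the lipase type (RHTO_03174) was 11.7-fold (6.30 to 24.01) higher in the library labelled Pi-replete, as were, chosen after their values were seen, a hormone-sensitive lipase also described as battenin (RHTO_02359, 3.66-fold, 2.80 to 4.84), a carnitine acetyltransferase (RHTO_01903, 3.96-fold, 3.30 to 4.79) and a thiolase (RHTO_00476, 3.22-fold, 2.88 to 3.60). The 14 phospholipid members divided evenly into 7 and 7 (median percentile 25.6), or 7 higher and 1 lower with equal totals, by construction. Without the 7 members described with another function, 1 was higher and 6 were lower. A gene described by KEGG as a lysophospholipase and by BLAST as an AMP-binding protein (RHTO_04785, 5.73-fold, 5.01 to 6.56) was higher in the library labelled Pi-limited.

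Amino acid biosynthesis genes were mostly lower in the library labelled Pi-limited, with 3 members higher and 24 lower, or 3 and 11 with equal totals. Their median log2 ratio was -1.27 (percentile 2.35). The number higher was below that of every one of the 10000 random lists, a measure added after the data were seen. The 3 higher members were described with another function as well, and without the 4 members of that kind 0 of 23 were higher. The members with the largest ratios included a pair of sulfur amino acid enzymes: a cystathionine beta-lyase (RHTO_05589) was 21.9-fold (18.2 to 26.5) and an O-acetylhomoserine (thiol)-lyase (RHTO_02616) 21.8-fold (17.0 to 28.5) higher in the library labelled Pi-replete. An alpha-aminoadipic semialdehyde synthase (RHTO_03324), an enzyme of lysine metabolism, was 16.1-fold (10.7 to 25.5) higher there. The nitrogen list had 14 members higher and 17 lower (median percentile 2.88), and its balance turned to 12 higher and 8 lower among members of at least 100 counts and to 13 and 6 without genes in more than 1 list. The amidases RHTO_06574 and RHTO_06576, which release ammonia from amides, were 14.5-fold (11.1 to 19.2) and 14.0-fold (10.4 to 19.3) higher in the library labelled Pi-replete. The 2 glutamate dehydrogenases, chosen after their values were seen, had opposite directions: the NAD-dependent enzyme (RHTO_07718), which is catabolic in yeasts, was 9.36-fold (8.56 to 10.3) higher in the library labelled Pi-replete, and the NADP-dependent enzyme (RHTO_04650), which assimilates ammonium, was 4.27-fold (3.76 to 4.87) higher in the library labelled Pi-limited. An ammonium transporter (RHTO_01846), chosen in the same way, had 352 and 49 counts, 6.88-fold (5.09 to 9.47) higher in the library labelled Pi-limited.

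DNA replication, chromatin and cell cycle genes were higher in the library labelled Pi-limited in 31 of 34 cases. Their median log2 ratio was 1.30 (percentile 97.0, or 94.5 with random lists not matched on expression). Their number higher exceeded that of every random list, a measure added after the data were seen. The small subunit of ribonucleotide reductase (RHTO_01070), which makes deoxyribonucleotides, had 3917 counts against 591, 6.35-fold higher (5.82 to 6.93). An ATP-dependent DNA helicase (RHTO_02787) was 13.6-fold (5.56 to 43.2) and a gene described as cell division control protein 24 (RHTO_02549) 5.64-fold (4.48 to 7.18) higher in the library labelled Pi-limited. Among members chosen after their values were seen, a histone H3 (RHTO_04185) was 3.64-fold (3.47 to 3.81), the replicative helicase subunit MCM5 (RHTO_07832) 2.78-fold (2.47 to 3.15) and the sliding clamp PCNA (RHTO_05685) 2.03-fold (1.80 to 2.29) higher there, although the log2 ratio of PCNA became -0.082 with median centring. With that centring, 4 members stayed at least 2-fold higher against 3 lower. Purine and pyrimidine genes gave 15 higher and 12 lower (median percentile 36.3), or 4 and 12 after median centring, by construction. Without the 15 members described with another function the split was 10 and 2, and at an FDR of at most 1e-10 it turned to 10 and 11. A purine nucleoside permease (RHTO_03772) was 12.3-fold (8.93 to 17.5) higher in the library labelled Pi-limited. The member of this list with the largest ratio, RHTO_05699 (102-fold, 83.6 to 126, higher in the library labelled Pi-replete), is an ATP-binding cassette protein that matched by the wording of its description.

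**Figure D2:**
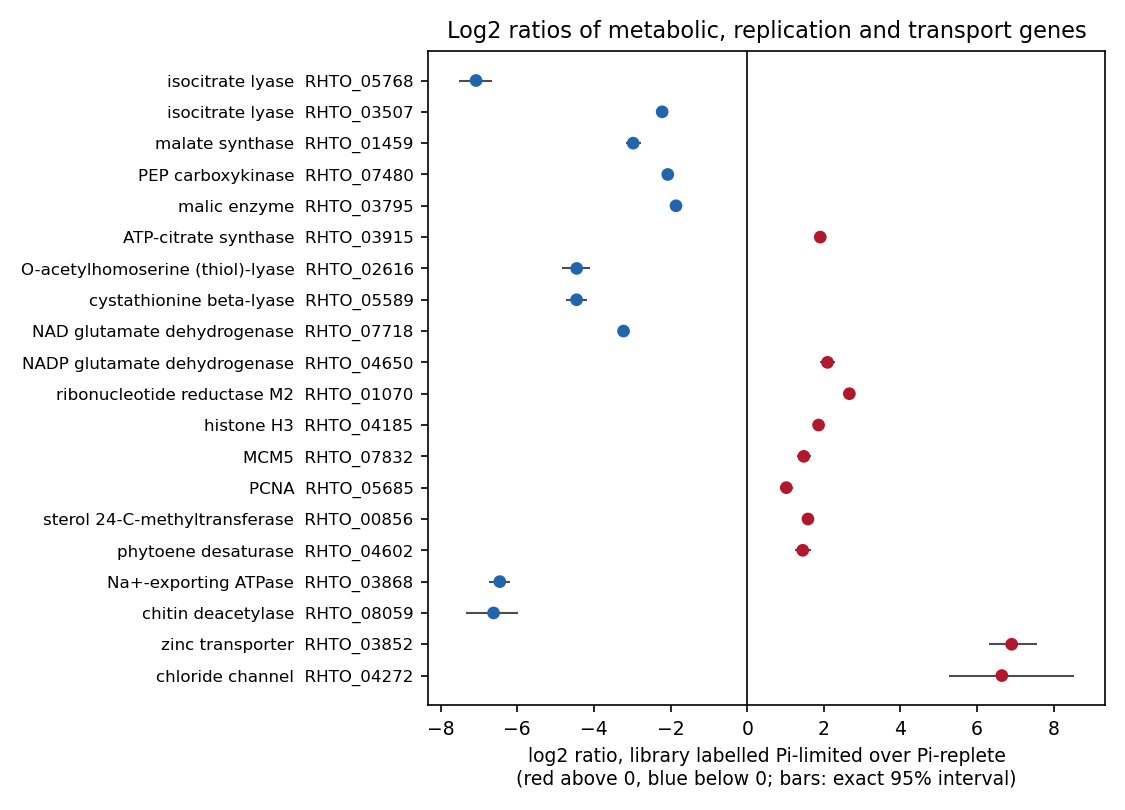
Log2 ratio of 20 named genes, library labelled Pi-limited over library labelled Pi-replete, with exact 95% intervals that cover counting error only (1 library each). The plotted isocitrate lyase genes (RHTO_05768 and RHTO_03507), malate synthase and sulfur amino acid genes lie to the left of 0. Replication, histone, sterol and zinc transporter genes lie to the right. RHTO_05767, also described as isocitrate lyase, had the other direction and is not plotted. The glutamate dehydrogenases, histone H3, MCM5 and PCNA were chosen after their values were seen.

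Carotenoid and sterol genes were higher in the library labelled Pi-limited in 10 of 12 cases (median percentile 75.0), and in 8 of 8 after members described with another function were left out, but median centring left 0 higher and 2 lower at 2-fold or more, where the 2 lower stay by construction. A sterol 24-C-methyltransferase of ergosterol synthesis (RHTO_00856) was 3.00-fold (2.69 to 3.35) and phytoene desaturase of carotenoid synthesis (RHTO_04602) 2.73-fold (2.36 to 3.17) higher there. Stress, chaperone and antioxidant genes gave 23 higher and 11 lower (median percentile 90.3), or 7 and 11 after median centring, by construction. RHTO_08116 is described by KEGG as the co-chaperone stress-induced phosphoprotein 1 and by BLAST as a proteophosphoglycan. It was 17.98-fold (11.8 to 28.7) higher in the library labelled Pi-limited. Whether it shares reads with other genes of that best hit is not known. A DnaJ protein (RHTO_02124) was 13.6-fold (10.2 to 18.5) higher in the library labelled Pi-replete. Heat shock protein 90 (RHTO_00789), chosen after its values were seen, had 12508 and 35867 counts, 3.00-fold (2.93 to 3.06) higher in the library labelled Pi-replete.

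Ribosome biogenesis and RNA polymerase I and III genes were lower in the library labelled Pi-limited in 12 of 16 cases (median log2 ratio -1.51, percentile 2.78). Ribosome assembly protein 1 (RHTO_07364) was 5.91-fold (5.51 to 6.34) higher in the library labelled Pi-replete. Ribosomal protein genes gave 5 higher and 2 lower (median percentile 62.5), or 0 and 2 after median centring, by construction, and the higher ones included bacterial-type proteins of the 50S class such as L35 (RHTO_07600, 3.22-fold, 2.74 to 3.79). Translation factors and aminoacyl-tRNA synthetases gave 7 higher and 8 lower (median percentile 35.6), or 7 and 4 with equal totals, by construction. A gene described as seryl-tRNA synthetase (RHTO_07643) had 152 and 11789 counts, 81.01-fold (69.0 to 95.7) higher in the library labelled Pi-replete, and translation initiation factor 6 (RHTO_07926) was 7.22-fold (6.68 to 7.82) higher there.

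Sugar and major facilitator transporters were lower in the library labelled Pi-limited in 40 of 58 cases, with a median log2 ratio of -1.56 (percentile 0.01). The list includes both PHS phosphate transporters. A multidrug transporter of the same superfamily (RHTO_07982) had the other direction and was 49.9-fold (25.1 to 116) higher in the library labelled Pi-limited, as was a hexose transporter chosen after its values were seen (RHTO_04266, 12914 and 1104 counts, 11.2-fold, 10.5 to 11.9). A gene described as peroxin-3 and as a major facilitator protein (RHTO_07802), which matched 3 lists, had 1 count against 112 (117-fold, 20.6 to 4661, higher in the library labelled Pi-replete). Ion transporters were among the named genes in both directions. A zinc transporter (RHTO_03852) had 2871 counts in the library labelled Pi-limited and 23 in the library labelled Pi-replete (119.5-fold, 79.5 to 189), and a voltage-gated chloride channel (RHTO_04272) had 418 and 4 counts (100.04-fold, 38.8 to 369). A sodium-exporting ATPase (RHTO_03868) had 108 and 9071 counts, 87.7-fold (72.6 to 107) higher in the library labelled Pi-replete. A PAS domain kinase (RHTO_01430) was 47.7-fold (26.4 to 96.1) and a gene described by KEGG as a heat shock or SKN7-type transcription factor and by BLAST as a chloride channel (RHTO_01721) 25.3-fold (12.6 to 59.3) higher in the library labelled Pi-limited.

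Cell wall and polysaccharide genes gave 14 higher and 12 lower (median percentile 86.1), or 3 and 12 after median centring, by construction. The balance also turned to 3 and 5 at 4-fold or more, to 7 and 9 at an FDR of at most 1e-10 and to 8 and 9 with at least 100 counts. Chitin deacetylase (RHTO_08059), which converts chitin to chitosan, had 20 and 1880 counts, 98.2-fold (63.4 to 161) higher in the library labelled Pi-replete, and an alpha-glucosidase (RHTO_00229) was 20.3-fold (11.4 to 39.7) higher in the library labelled Pi-limited. Autophagy, vacuole and proteolysis genes divided into 11 and 11 (median percentile 30.8), or 11 higher and 7 lower without 4 members described with another function, which turned the median log2 ratio to 1.20. By construction, median centring gave 6 and 11 and equal totals 11 and 8. A saccharopepsin, a vacuolar protease (RHTO_06029), was 10.2-fold (8.71 to 11.97) higher in the library labelled Pi-replete. As a check on other cell states, the mating and sporulation list gave 3 higher and 2 lower (median percentile 54.9), or 0 and 2 after median centring, by construction, among them the meiotic recombination gene SPO11 (RHTO_06964, 12 and 86 counts). The list of organelle-encoded and structural RNA, kept as a sign of RNA quality, matched 0 listed genes. Nearly all listed genes have coding lengths, and only genes past the thresholds are listed, so this says nothing of RNA quality.

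**Figure D3:**
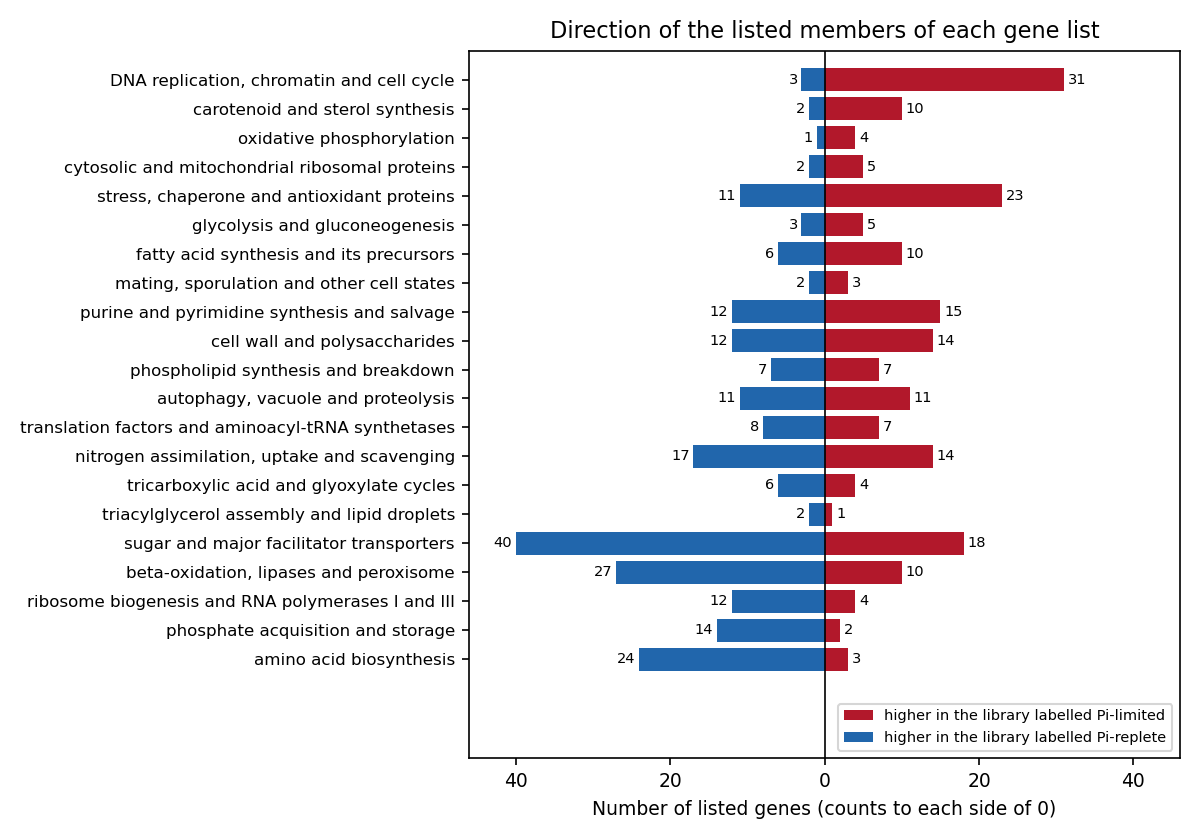
Number of listed members of each gene list that were higher in the library labelled Pi-limited (red, right of 0) or higher in the library labelled Pi-replete (blue, left of 0), for the 21 lists with a listed member. Amino acid biosynthesis (24 against 3) and phosphate acquisition (14 against 2) have the largest blue shares, and DNA replication, chromatin and cell cycle (31 against 3) the largest red share. Where a shift of all genes turns the balance of a list near the middle, it does so by construction.

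The table holds only genes past the authors' thresholds, so the lists describe listed members and not whole pathways.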

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

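The percentile of the number of members higher and the lists without members described with another function were chosen after the data were seen, and all other settings before. A shift of all genes cannot turn a list that already leans its way, so median centring says nothing of lists that lean lower, and equal totals nothing of lists that lean higher. The phosphate acquisition list kept its lower balance under every setting run, from 7.14% to 16.7% of members higher in the library labelled Pi-limited against 12.5% as deposited. Amino acid biosynthesis, beta-oxidation, sugar and major facilitator transporters, and DNA replication also kept their side under every setting run. Of 548 values of genes named by the fixed rule under an alternative, 1 changed sign (RHTO_05464, -0.017 with median centring), and of 177 of genes named after their values were seen, 3 did with the same centring: RHTO_05685 (-0.082), RHTO_05455 (-0.0064) and RHTO_04120 (-0.095). Depth limits low genes most: RHTO_05069, with 4 counts in 1 library, has an interval from 25.3- to 242-fold. In the values that follow, a share is the percent of a list's members higher in the library labelled Pi-limited and a median is its log2 ratio, and a cause is given only where the setting's construction gives it.

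Centring on the median shifts every gene down in a table without differences under 2-fold, so by construction no lower gene was lost and genes listed higher dropped from 817 to 181. Shares became 0 for amino acid biosynthesis, ribosome biogenesis, translation and the tricarboxylic acid cycle, 10 for beta-oxidation, 13.04 for sugar and major facilitator transporters, 15 for nitrogen and 57.1 for DNA replication. Direction turned for cell wall (share 20, median -2.93), fatty acid synthesis (14.3, -3.12), purines and pyrimidines (25, -2.35) and stress (38.9, -2.21). Equal totals shift every gene up, so by construction only lower genes were lost: the share of phospholipid genes became 87.5, the medians of autophagy (1.35) and phospholipid genes (1.65) turned, and translation turned in both (63.6, 1.52).

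With an absolute log2 ratio of at least 2, which keeps fewer genes, 197 were higher and 277 lower. Cell wall (37.5, -2.38) and fatty acid synthesis (20, -2.82) turned, and shares became 0 for amino acid biosynthesis and ribosome biogenesis and 23.5 for nitrogen. With an FDR of at most 1e-10, 496 genes were higher and 470 lower, cell wall (43.8, -1.42), glycolysis (40.0, -1.02) and purines and pyrimidines (47.6, -1.10) turned, and the share of beta-oxidation became 11.1. With at least 100 counts, cell wall (47.1, -1.18), glycolysis (40.0, -1.02) and nitrogen (60.0, 1.15) turned.

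Without genes in more than 1 list, nitrogen (68.4, 1.20) and the median of the tricarboxylic acid cycle (0.037) turned, and the share of carotenoid and sterol genes became 100. Without members described with another function, glycolysis (40.0, -1.02) and the median of autophagy (1.20) turned, and shares became 0 for amino acid biosynthesis, 100 for carotenoid and sterol genes, 14.3 for phospholipids and 83.3 for purines and pyrimidines. The cause was not tested beyond the change of members or genes that each setting makes. Pseudocounts of 1 and 0.1 gave 745 and 807 genes higher against 562 and 584 lower and turned no list. With unmatched random lists the percentile of the median was 0.32 for nitrogen, 2.21 for ribosome biogenesis, 97.98 for glycolysis and 2.58 for amino acid biosynthesis. No paired analysis was possible because each condition has 1 library and the labels carry no replicate numbers.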

Other observations

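The gene groups in the next 2 paragraphs, and the tests of the 3 patterns after them, were chosen after the results were seen. Only the direction of the phosphate acquisition list was fixed before as a check of the labels.

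Among gene groups that partly overlap the fixed lists, 7 of 8 listed genes described as monocarboxylate transporters or permeases were lower in the library labelled Pi-limited, led by RHTO_05656 (56 and 473 counts, 8.82-fold, 6.68 to 11.9, higher in the library labelled Pi-replete). Of these 8 genes, 6 are also members of a fixed list. Of 10 ATP-binding cassette proteins, 4 of them in a fixed list, 7 were lower there, and a pleiotropic drug resistance transporter (RHTO_02583) had 366 counts in the library labelled Pi-limited and 24530 in the library labelled Pi-replete, a 70.0-fold difference (63.1 to 77.8). All 5 listed genes described as heat shock transcription factors, which are members of the stress list as well, were higher in the library labelled Pi-limited. The folds were 2.37 to 25.3, while heat shock protein 90 was lower. The largest was that of RHTO_01721, described by BLAST as a chloride channel, and the next was 5.33-fold (RHTO_06778). Under median centring, a shift of -1.10 on the log2 scale, 2 of the 5 heat shock factors and 0 of the 3 ATP-binding cassette genes with the other direction stayed at least 2-fold higher, and RHTO_05455 and RHTO_04120 of the latter turned in sign.

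Metal and ion transport genes went both ways, with 9 of 20 higher and 11 lower in the library labelled Pi-limited. By construction, this became 9 and 8 with equal totals and 6 and 11 with median centring. Of the 20, 4 are also members of a fixed list. Among them is RHTO_01721, described by KEGG as a heat shock factor and by BLAST as a chloride channel, which matched by that wording. A ferric-chelate reductase (RHTO_06556) had 16711 and 1328 counts, 12.05-fold (11.4 to 12.7) higher in the library labelled Pi-limited, and a copper transporter (RHTO_02838) was 5.99-fold (5.53 to 6.49) and a magnesium transporter (RHTO_01650) 4.39-fold (3.66 to 5.31) higher there. A siderophore transporter (RHTO_07321) was 20.8-fold (10.3 to 48.9) higher in the library labelled Pi-replete. A thiazole biosynthetic enzyme of thiamine synthesis (RHTO_05679) had 32630 and 9199 counts, 3.40-fold (3.32 to 3.48) higher in the library labelled Pi-limited. Among genes at 0 in 1 library, RHTO_04817 had 144 counts in the library labelled Pi-limited (at least 45.95-fold higher) and RHTO_03453 had 206 counts in the library labelled Pi-replete (at least 71.7-fold higher), against a floor of 3 counts per library. Genes with a proteophosphoglycan best hit were higher in the library labelled Pi-limited in 68 of 111 cases, beside 58.3% of all listed genes. Median centring left 19 of them higher and 43 lower by construction. Any copies among them may share reads, but sequences were not compared.

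The direction of the phosphate acquisition genes against the labels is the pattern that bears most on the rest. The library totals differ by a ratio of 1.04, with the larger total in the library labelled Pi-limited, where these genes were mostly lower. A difference in depth of that size is too small to give their folds, which are already divided by the totals. The smallest lower limit of the fold over the 4 phosphate transporter genes was 22.5. Every listed gene passed a 2-fold filter, so that limit is no separate test of depth. An exchange of the labels, or of the sample names that tie the table's columns to them, would turn each direction in the report, and cannot be told apart from a true difference between the cultures with 1 library each. The fixed check of the labels went against them, with 14 of 16 members lower in the library labelled Pi-limited. The same observation raised this explanation, so it is no separate test of an exchange. The sample names are separate information: the library labelled Pi-limited is named control_F3A and the library labelled Pi-replete P0A, and neither name is explained in the sources used here.

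Short genes were more often higher in the library labelled Pi-limited: the share was 73.2% of the 284 genes with the shortest coding lengths and 48.8% of the 281 with the longest, of 5 length classes, a gap of 24.5 percentage points (95% interval 16.5 to 32.0). Unannotated short gene models are argued against, since the gap was 39.4 points (27.9 to 49.0) among genes with a KEGG entry. Low counts are argued against as the whole cause by the highest of 3 classes of summed counts. The gap there was 39.7 points (25.1 to 51.6). The intervals of the middle class (7.87, -4.997 to 20.4) and the lowest (12.6, -2.83 to 28.6) included 0. The share of the longest genes was 32.9% in the highest class, 68.5% in the middle and 58.7% in the lowest. That of the shortest was 72.6%, 76.3% and 71.3%. The gap thus varied with counts, and a part of counts in the gap over all listed genes is not excluded. A length-dependent bias between the library preparations cannot be told apart from a difference in the cells with 1 library each. Among genes in no fixed list the gap was 21.0 points (11.9 to 29.7). Intervals of these gaps take genes as independent draws and may be too narrow, since neighbouring listed genes leaned to the same library.

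Neighbouring listed genes leaned to the same library: of 293 pairs of listed genes next to each other in the gene table of strain NP11, 65.5% (59.8 to 71.0) had the same direction, against a mean of 51.3% and a highest value of 62.8% in 10000 shuffles. Tandem copies with a shared description are argued against as the whole cause, since pairs without one gave 64.8% (58.8 to 70.5). Sequences were not compared, so copies with different descriptions may remain among those pairs. Pairs with RPKM within 3-fold of each other gave 67.4% (59.0 to 75.0), and pairs 3-fold or more apart gave 63.8% (55.6 to 71.4). The lean was thus not confined to pairs of unequal RPKM. Whether reads of a strong gene were counted in its weaker neighbour cannot be decided from this split. The RPKM values already include any such reads. Intervals in this paragraph take pairs as independent draws and may be too narrow. Overlapping transcripts of similar strength may still contribute, and shared regulation of neighbours in this yeast remains a hypothesis that these 2 libraries could not test.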
